A study of Homo sapiens with 114 samples.

How the data were processed

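Total RNA of cultures of human mesenchymal progenitor cells was extracted with the RNeasy Mini Kit, made into libraries by Nextera tagmentation and sequenced by 3' digital gene expression. The deposited table, made by the authors, holds 1 column of counts per library for 22794 gene symbols, 683 of them without a count in any library. The values are whole numbers whose totals differ between libraries, from 31525 to 8557124, so they were taken as raw counts that had not been normalised. The genome build was hg38 per the labels. The aligner, the counting tool, the annotation, and whether reads with the same molecular barcode were counted once are not given in the sources used here. All columns were used.

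Groups were taken from the labels of each library, which give the ORF pool (26 constructs or none), the oncogene (EWS-FLI1 or vector), the evolution experiment and the passage (1, 4 or 8). Replicates carry the letters a to e. The letters were not used as pairs. Fits were made in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr on the 24 groups, which left 10062. Libraries were scaled by TMM, and 1 edgeR quasi-likelihood model with a mean for each of the 24 groups was fitted to all libraries. Each of the 18 comparisons was a contrast within each experiment, averaged with a weight of 0.5 for each of the 2 experiments, tested two-sided with Benjamini-Hochberg adjustment over all kept genes at 0.05. The same contrast was also tested in each experiment alone, and the difference between the experiments was tested as a contrast of its own. The standard error of a log2 fold change was taken from the fold change and the quasi-likelihood F statistic. The overlap chance gives is the product of both experiments' counts in one direction divided by the number of genes tested.

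A total of 26 gene lists was fixed before the data were examined, along with the comparisons, the tests and all alternatives but 3. They cover genes induced and repressed by EWS-FLI1, p53 targets, replication fork protection, DNA replication, mitosis, cohesin, secreted factors of senescent cells, extracellular matrix, actin with SRF and YAP targets, the amino acid and unfolded protein response, cholesterol synthesis, hypoxia with glycolysis, interferon response, immediate early genes, cancer genes of the long arm of chromosome 8, and mitochondrially encoded genes. The others hold markers of mesenchymal surface, osteogenic, adipogenic, chondrogenic, neural, epithelial, endothelial, blood and skeletal muscle cells. A lookup of older gene symbols was added after the table was opened. A member missing from the table was sought under an older symbol belonging to that gene alone. Lists with at least 3 tested members were tested with camera (limma) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 20 lists within a comparison. CDKN1A, COL1A1, THBS1 and some other genes stand on more than 1 list. Chromosomes were tested in the same way. A list's score in a library is the mean of log2(CPM + 1) over its members.

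Genes named in the text were chosen by a rule fixed at the same time. FLI1, EWSR1, RAD21 and MYC were included in every comparison whatever their values, though the text does not print all of them for each. To these were added, for each comparison, up to 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold over both experiments and in each alone with the same sign, with a mean of at least 10 CPM in the higher group, and up to 4 members of each list with the smallest adjusted p. Genes without an approved symbol, XIST, TSIX and Y-linked genes were left out. A fold against a group without counts is a lower bound computed with 3 counts over the group. With 1 to 3 counts the ratio has an exact 95% binomial interval.

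The alternatives planned were each experiment alone, no filter, a stricter filter (1 CPM in 25% of libraries), DESeq2 size factors, a block for the replicate letter, DESeq2, counts summed per group, only the libraries compared, each replicate letter left out in turn, and a minimum of 10 CPM for chromosomes. Chosen after the data were seen were fits without the 6 libraries above 3000000 counts, without the library with the lowest total, and with libraries thinned to 1000000 counts. A count was held to have moved when it changed by more than 1.5 times. In no comparison did DESeq2 size factors move the median of all genes by more than 0.1, and 0 genes were called in opposite directions by both scalings. Other splits of the same libraries, at most 100 per comparison and within experiments, were drawn with a fixed seed and tested with limma-voom.

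The pipeline was tested on counts simulated for all 114 libraries from 1 common profile and the fitted dispersions. Changes were put only into EWS-FLI1 cells without the pool at passage 8, which were compared with vector cells. The simulation held no other difference between passages or experiments, so the figures hold for that comparison and that setting only. A change was given to 200 genes, of which 62 at 1.5-fold, 63 at 2-fold and 65 at 4-fold passed the filter. Of these edgeR found 46.8, 82.5 and 98.5%, and it called 6 unchanged genes. DESeq2 found 41.9, 81 and 98.5%, limma-voom 45.2, 79.4 and 96.9%, and edgeR on summed counts 41.9, 79.4 and 98.5%. With the first experiment alone edgeR found 19.4, 54 and 87.7%, so a gene that fails in a single experiment may still have changed there. camera called the changed list and 0 of 25 random lists. The counts of each gene were drawn independently of other genes, so this does not show how camera errs on lists whose members move together. Replicates were checked for duplicated libraries. In 218 pairs of replicates the chi-square per gene ran from 1.23 to 11.97, and no pair agreed as closely as repeated sequencing of 1 library would.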

Results

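Human mesenchymal progenitor cells, stromal cells that can form several connective tissues, were infected with a doxycycline-induced lentivirus for EWS-FLI1, the fusion oncogene of Ewing sarcoma, or with its empty vector. Each kind of cell was also grown with or without a lentiviral pool of 26 open reading frames (ORFs) driven by a CMV promoter. Doxycycline (1 µg/mL) stayed in the medium, and RNA was taken at passages 1, 4 and 8 of a first and a second evolution experiment. The libraries fall into 24 groups by pool, oncogene, experiment and passage. Groups held 5 libraries, except vector cells of the first experiment at passage 8 with and without the pool (3 each), EWS-FLI1 cells without the pool at the same point (4) and EWS-FLI1 cells with the pool at passage 1 of the second experiment (4). The members of the pool are not named in the sources used here.

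RNA was measured by 3' digital gene expression, which counts reads near the 3' end of transcripts. Library totals ran from 31525 to 8557124 counts with a median of 683546, and the median was 895116 in the first experiment and 495168 in the second. Above 3000000 counts stood 6 libraries, all of the second experiment, and 8 libraries had under 250000. The 10062 genes kept for testing hold 99.1% of all counts. Values are counts per 1000000 counts (CPM) ± SD between libraries, or log2 fold changes ± SE averaged over both experiments. P-values measure the spread between these libraries alone, since the labels do not say whether replicates were infected or grown apart, and bounds and intervals cover counting error only.

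**Figure D1:**
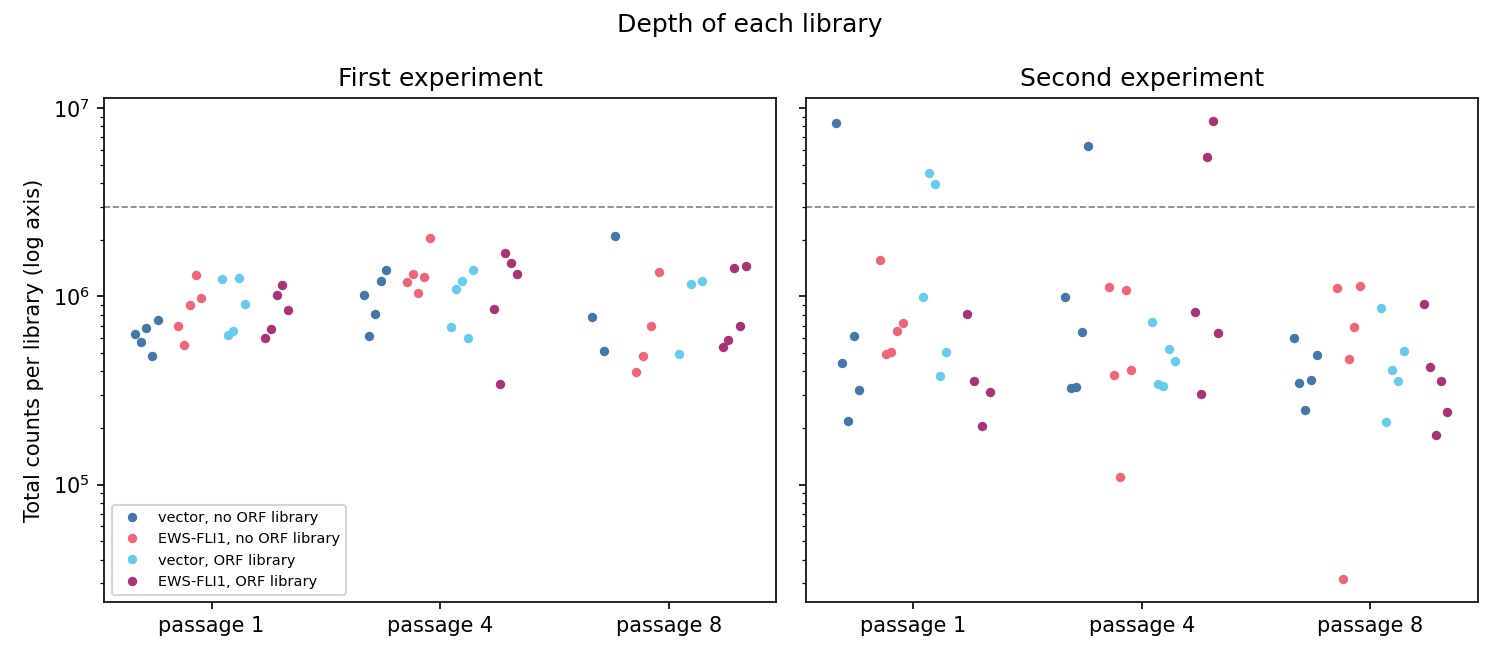
Total counts of each library (points, log axis) by group, with a dashed line at 3000000 counts. The 6 libraries above the line, up to 8557124 counts, all belong to the second experiment.

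EWS-FLI1 joins part of EWSR1 (GRCh38 chromosome 22, 29268268 to 29300521) to part of FLI1 (chromosome 11, 128685132 to 128813267). Group means were 8.39 to 21.8 CPM for FLI1 and 44.9 to 96.4 CPM for EWSR1 over all groups, with and without the oncogene. Whether reads of the construct enter these counts is not given in the sources used here, so they cannot be read as levels of the transgene. RAD21 (chromosome 8, 116845934 to 116874776), the cohesin subunit that the series title names, and MYC (chromosome 8, 127735434 to 127742951), a growth regulator, were tested in every comparison. MYC is printed for only some of them. As the pool's members are not named, whether construct reads enter the counts of RAD21 or MYC in cells with the pool is open.

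What EWS-FLI1 alone did to these cells was asked first. At passage 1, EWS-FLI1 cells held more mRNA of CXCL8 and CXCL1, which code for attractants of neutrophils, than vector cells (n = 10 and 10 libraries). CXCL8 (chromosome 4, 73740569 to 73743716) was 7.51-fold higher (log2 2.91 ± 0.13) and CXCL1 (chromosome 4, 73869393 to 73871308) 6.8-fold (log2 2.77 ± 0.10), and both were higher in every EWS-FLI1 library than in any vector library of the same experiment. CXCL1 stood at 2841 ± 263 against 743 ± 95.8 CPM in the first experiment (n = 5 each) and at 882 ± 125 against 66.4 ± 18.7 CPM in the second (n = 5 each). The inflammatory cytokine IL1B (2.40 ± 0.12), the collagenase MMP1 (1.02 ± 0.05) and the collagen gene COL5A3 (3.12 ± 0.30) also rose. Among the genes that fell were DIO2, which activates thyroid hormone (-2.07 ± 0.12), the activin antagonist FST (-1.63 ± 0.11) and the oxytocin receptor gene OXTR (-1.61 ± 0.11). ITM2A, which codes for a membrane protein and stands on the list of EWS-FLI1-induced genes, had no count in vector cells and was at least 29-fold higher in the first experiment and at least 13-fold in the second.

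Of 21 tested secreted factors of the senescent type, 12 were higher and 2 lower at passage 1 (14 and 3 adjusted over the list alone, median 0.76, camera adjusted p = 2.85e-62). Extracellular matrix genes gave 12 of 29 higher, such as POSTN (0.53 ± 0.07), and 0 lower (15 and 1 adjusted over the list alone, adjusted p = 3.89e-10). Targets of actin, SRF and YAP signalling, which read out the contractile state, had 7 of 18 lower, among them ACTG2 (-0.83 ± 0.06) and TAGLN (-0.47 ± 0.06), and 0 higher (0 and 8 adjusted over the list alone, adjusted p = 1.07e-11). The amino acid and unfolded protein response list had 6 of 14 higher, with ATF4 at 0.56 ± 0.10 and ASNS at 0.95 ± 0.16 (7 adjusted over the list alone, adjusted p = 3.61e-07). Genes known as repressed by EWS-FLI1 in Ewing cells moved up here, 6 of 17 against 1 lower (8 and 3 adjusted over the list alone, adjusted p = 1.36e-05). They included COL1A2, a fibrillar collagen (0.39 ± 0.05), and IER3, an early response gene (0.73 ± 0.08). Of 14 tested genes known as induced by EWS-FLI1, 2 were higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.185). RAD21 was not called (0.29 ± 0.14, adjusted p = 0.296), and neither were FLI1 (-0.18 ± 0.22, adjusted p = 0.853), EWSR1 (0.05 ± 0.11, adjusted p = 0.993) and MYC (-0.11 ± 0.22, adjusted p = 0.933). edgeR called 501 genes, 298 higher and 203 lower, with 274 in the first experiment alone and 321 in the second. In both, 93 moved the same way, where chance gives 3.19 higher and 1.36 lower. MMP1 did not pass in the first experiment alone (adjusted p = 0.604), nor ATF4 in the second (adjusted p = 0.0621). The effects on CXCL8 (1.79 and 4.03) differed between the experiments (adjusted p = 1.15e-11).

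At passage 4 (n = 10 and 10), EWS-FLI1 cells without the pool still had more MMP1 (1.39 ± 0.05), CXCL8 (1.32 ± 0.12) and FLT1, a VEGF receptor gene (1.74 ± 0.15), than vector cells. The carboxypeptidase gene CPA4 (-2.02 ± 0.14), OXTR (-1.49 ± 0.11) and the smooth muscle actin gene ACTG2 (-1.12 ± 0.06) were lower. Secreted factors had 7 higher and 2 lower (10 and 4 adjusted over the list alone, adjusted p = 2.64e-18). Matrix genes had 10 and 1 (12 and 1 adjusted over the list alone, adjusted p = 3.79e-10). Hypoxia and glycolysis genes fell, 6 of 13 with 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.000341), as BNIP3 (-0.83 ± 0.10) and PGK1 (-0.35 ± 0.06, and adjusted p = 0.18 in the second experiment alone) show. RAD21 and MYC were not called over both experiments. For RAD21, 5 of 5 EWS-FLI1 libraries stood above all vector libraries in the first experiment, and in the second 1 stood above and 1 below. In all, 385 genes passed, 203 higher and 182 lower, with 308 and 369 in the experiments taken singly and 54 shared in direction (chance 3.00 and 2.65). Without replicate e of every group the count was 224, and the actin list, lower over both experiments (adjusted p = 0.00016), was not called in the second alone (adjusted p = 0.655).

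At passage 8 the cells without the pool differed in genes of cell division (EWS-FLI1 n = 9, vector n = 8). MKI67 (chromosome 10, 128096659 to 128126423), a marker of cycling cells, stood at 27.4 ± 11.4 CPM in EWS-FLI1 cells of the first experiment (n = 4) and rested on 1 count over 3 vector libraries. In the second experiment it stood at 29.3 ± 37.0 against 1.64 ± 1.56 CPM (n = 5 each), and at 12.8 ± 4.08 CPM (n = 4) without replicate b of EWS-FLI1 cells, a library of 31525 counts with 95.2 CPM. TOP2A, the topoisomerase of dividing cells, rose by 3.22 ± 0.26 and the kinetochore gene CENPF by 2.48 ± 0.19, and the complement gene C3 by 5.24 ± 0.26. CXCL8 rose by 5.11 ± 0.18, with 9.27 in the first experiment and 0.95 in the second. FST (-3.46 ± 0.13), CPA4 (-2.57 ± 0.12) and MEST (-2.96 ± 0.26), an imprinted gene of mesoderm, fell.

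Of 20 mitosis genes 16 were higher and 0 lower (19 and 0 adjusted over the list alone, median 2.76, or 2.01 with genes without counts in a group at their bound; adjusted p = 4.1e-19). DNA replication genes had 8 of 25 higher, such as MCM7 (0.99 ± 0.20, with adjusted p = 0.058 without replicate e), and 0 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0498, and 0.0867 without the 6 libraries above 3000000 counts). A replicate block also ended this list call. Replication fork protection genes had 6 of 24 higher (6 adjusted over the list alone, adjusted p = 0.00865; 0.179 in the second experiment alone). Secreted factors had 14 higher and 2 lower (15 and 3 adjusted over the list alone, adjusted p = 2.43e-82). Mesenchymal surface markers had 6 of 11 higher, NT5E among them (1.59 ± 0.09), and 2 lower (the same counts adjusted over the list alone, adjusted p = 1.49e-05). Neural genes had 5 of 8 and 1, with STMN2 at 2.61 ± 0.20 (5 and 2 adjusted over the list alone, adjusted p = 0.00191). Of 3 osteogenic genes 2 fell, SPP1 (-1.91 ± 0.38) and SPARC (-0.42 ± 0.05, with 0.0076 in the second experiment), with 2 adjusted over the list alone (adjusted p = 0.00925). For RAD21 the value was -0.14 ± 0.17, adjusted p = 0.714. Genes called numbered 1294 (689 higher, 605 lower), 1573 in the first experiment, 541 in the second, 218 shared in direction (chance 22.9 and 19.3) and 849 without replicate e. The effect differed between experiments for 883 genes. The actin list fell in the average (adjusted p = 4.76e-10) and was not called in the second experiment (adjusted p = 0.603).

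**Figure D2:**
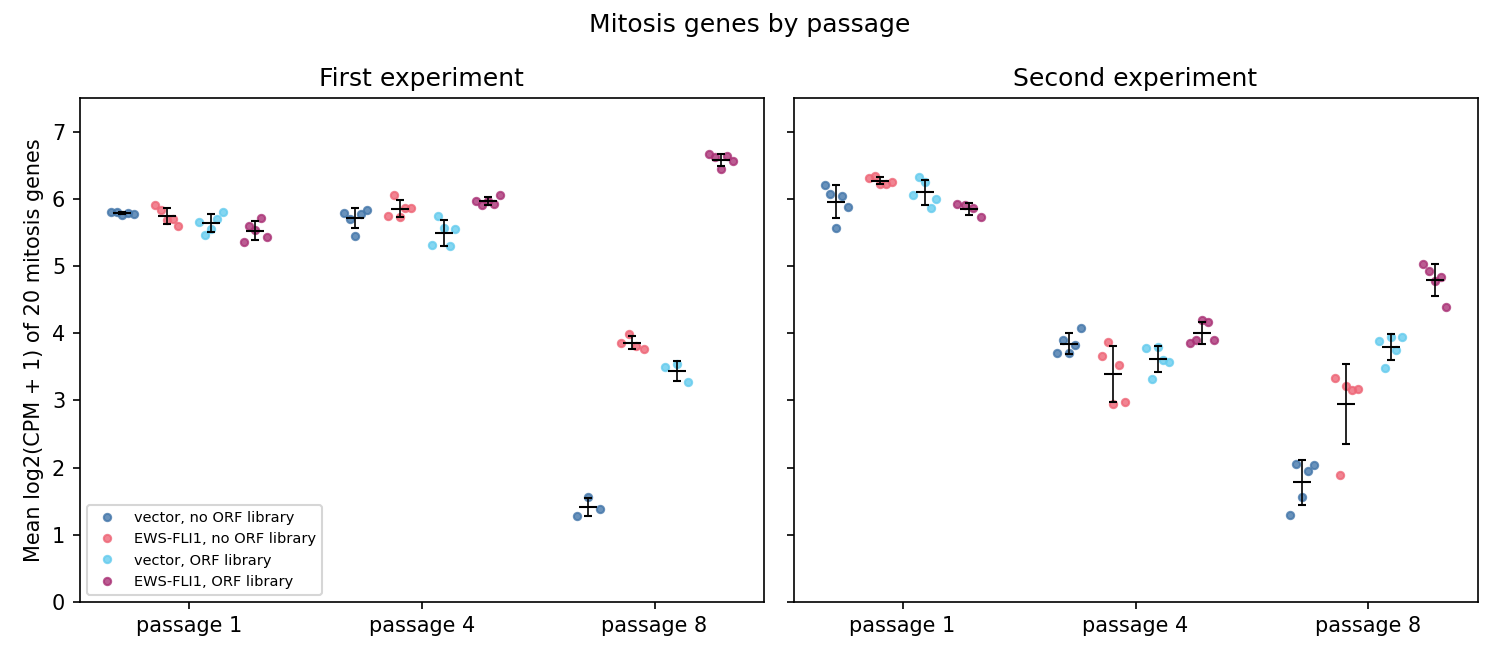
Mean of log2(CPM + 1) over 20 mitosis genes in each library (points) by passage, with the mean and SD of each group (black bars), for both experiments. At passage 8 every group with the pool stood above its counterpart without it, as in the first experiment at 6.58 ± 0.09 against 3.86 ± 0.10 in EWS-FLI1 cells and 3.44 ± 0.15 against 1.41 ± 0.14 in vector cells.

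The effect of EWS-FLI1 in cells that also carried the pool was asked next. At passage 1 (n = 9 and 10), FLT1 (2.15 ± 0.14), COL5A3 (3.66 ± 0.28), IL1B (1.46 ± 0.09) and the matrix protein gene THBS1 (0.98 ± 0.07) were higher, and DIO2 (-1.81 ± 0.13) and the growth factor gene FGF7 (-2.15 ± 0.26) lower. IL1B had -0.05 in the first experiment and 2.97 in the second. The actin, SRF and YAP targets moved up here, 8 of 18 higher and 1 lower (11 and 2 adjusted over the list alone, adjusted p = 7.27e-14). CTGF, a YAP target, rose by 0.95 ± 0.09, and ANKRD1, another, by 1.34 ± 0.09, which was 2.65 in the first experiment and 0.03 in the second. Matrix genes had 16 of 29 higher and 1 lower (18 and 2 adjusted over the list alone, adjusted p = 8.38e-24). Secreted factors had 11 and 1 (the same adjusted over the list alone, adjusted p = 8.38e-24), and genes known as repressed by EWS-FLI1 10 and 1 (11 and 1 adjusted over the list alone, adjusted p = 3.45e-25). The mitosis list was lower as a set (adjusted p = 0.0245) with 0 of 20 genes called by edgeR, over all genes and adjusted over the list alone, 5 at an unadjusted p under 0.05 and 2 called by DESeq2. That call ended with an estimated correlation (adjusted p = 0.111) and without the 6 libraries above 3000000 counts (adjusted p = 0.144). Cholesterol synthesis genes had 4 of 15 higher (4 adjusted over the list alone, adjusted p = 0.0278), or 1 without those 6 libraries, and RAD21 was not called (0.07 ± 0.14, adjusted p = 0.825). The 849 genes called (525 higher, 324 lower) became 377 without those 6 libraries, 421 without replicate b and 340 without replicate c. The experiments gave 230 and 1410 genes, with 81 shared in direction (chance 12.4 and 3.86).

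Passage 4 of the cells with the pool (n = 10 and 10) again had CXCL1 (2.46 ± 0.12), CXCL8 (1.66 ± 0.11) and TNFRSF11B, a decoy receptor of bone turnover (1.68 ± 0.11), higher with EWS-FLI1, and THY1, a mesenchymal surface marker (-2.01 ± 0.14), and ACTG2 (-1.26 ± 0.06) lower. Mitosis genes had 6 of 20 higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 4.28e-05), or 2 without the 6 libraries above 3000000 counts, with the cyclin gene CCNB1 at 0.49 ± 0.12 and CENPF at 0.42 ± 0.10. Neither passed in the second experiment alone, and CCNB1 did not pass without replicate c (adjusted p = 0.0867) or without those 6 libraries (adjusted p = 0.163). Replication genes had 3 of 25 higher (3 adjusted over the list alone, adjusted p = 0.0329, and 1 higher with adjusted p = 0.0525 without those 6 libraries). Actin, SRF and YAP targets had 9 of 18 lower and 1 higher (9 and 3 adjusted over the list alone, adjusted p = 2.54e-09). Secreted factors had 9 of 21 higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 1.41e-15). Matrix genes, 10 higher and 3 lower (12 and 3 adjusted over the list alone, adjusted p = 0.000203), lost their call with an estimated correlation (adjusted p = 0.0778). Without those 6 libraries they had 14 higher and 1 lower (adjusted p = 1.59e-15, and 2.98e-06 with an estimated correlation). The change in RAD21 did not pass (-0.18 ± 0.14, adjusted p = 0.461). Over both experiments 1019 genes passed (534 higher, 485 lower), 254 in the first and 1229 in the second alone, 91 of them shared in direction (chance 7.79 and 7.35). The count was 335 without the 6 libraries above 3000000 counts, 312 without replicate c and 395 without replicate d.

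At passage 8 in the cells with the pool, EWS-FLI1 cells stood far above vector cells in cell division genes, CXCL1 and CXCL8 (n = 10 and 8). MKI67 reached 244 ± 34.4 CPM (n = 5) against 14.8 ± 2 (n = 3) in the first experiment and 67.5 ± 11.4 against 22.4 ± 5.92 in the second (n = 5 each), a log2 change of 2.82 ± 0.20. CXCL1 rose by 5.02 ± 0.14 and CXCL8 by 4.92 ± 0.15, and the levels of CXCL8 were 1209 ± 134 against 32.8 ± 10.5 CPM in the first experiment and 473 ± 39.7 against 21.4 ± 4.64 in the second. RAD21 rose by 0.64 ± 0.16 (adjusted p = 0.00107). It stood at 92.5 ± 10.8 against 40.6 ± 5.70 CPM in the first experiment, where all 5 EWS-FLI1 libraries lay above all 3 vector libraries, and at 58.2 ± 14.1 against 51.2 ± 12 CPM in the second, where it did not pass (0.08, adjusted p = 0.993). The effects differed (adjusted p = 0.0105). CPA4 (-3.09 ± 0.12), the keratin-associated gene KRTAP4-9 (-3.39 ± 0.20) and the bone matrix gene SPP1 (-2.85 ± 0.36) fell.

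All 20 mitosis genes were higher (20 adjusted over the list alone, median 2.10, adjusted p = 2.2e-51), as were 20 of 25 replication genes (21 adjusted over the list alone, adjusted p = 7.26e-14), 13 of 24 fork protection genes (14 adjusted over the list alone, adjusted p = 2.2e-09) and 7 of 14 cohesin genes (7 adjusted over the list alone, adjusted p = 0.000222), with none lower. Examples are the helicase subunit MCM7 (2.12 ± 0.17), the checkpoint mediator CLSPN (2.61 ± 0.19), the cohesin subunit SMC1A (0.98 ± 0.15) and the cohesin acetyltransferase ESCO2 (2.83 ± 0.46). In the second experiment alone the replication (adjusted p = 0.0827), fork (adjusted p = 0.131) and cohesin (adjusted p = 0.346) lists were not called, nor were SMC1A (adjusted p = 0.553) and ESCO2 (adjusted p = 0.099). Targets of p53 had 9 of 24 lower, the polymerase gene POLH among them (-1.09 ± 0.16), and 0 higher (the same adjusted over the list alone, adjusted p = 0.000458; 0.0843 in the second experiment). Actin, SRF and YAP targets had 14 of 18 lower, such as TAGLN (-1.18 ± 0.06), and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 2.75e-26). Secreted factors had 12 higher and 4 lower (12 and 5 adjusted over the list alone, adjusted p = 1.73e-38). Matrix genes, 4 higher and 6 lower (4 and 7 adjusted over the list alone, adjusted p = 0.039), lost their call with an estimated correlation (adjusted p = 0.306) and were higher in the second experiment (adjusted p = 0.0174). FLI1 was lower (-1.01 ± 0.30, adjusted p = 0.00796) and EWSR1 higher (0.44 ± 0.13, adjusted p = 0.0078). Neither passed in the second experiment or without replicate a (adjusted p = 0.2 and 0.097), nor did EWSR1 without replicate c (adjusted p = 0.0551). MYC did not pass (-0.56 ± 0.29, adjusted p = 0.18) except without replicate a (-1.17, adjusted p = 0.00779). The comparison called 1850 genes, 876 higher and 974 lower (1046 and 791 with DESeq2 size factors), 2393 in the first experiment and 488 in the second, 273 shared in direction (chance 31.1 and 26.2). The effects of 841 genes differed between the experiments.

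**Figure D3:**
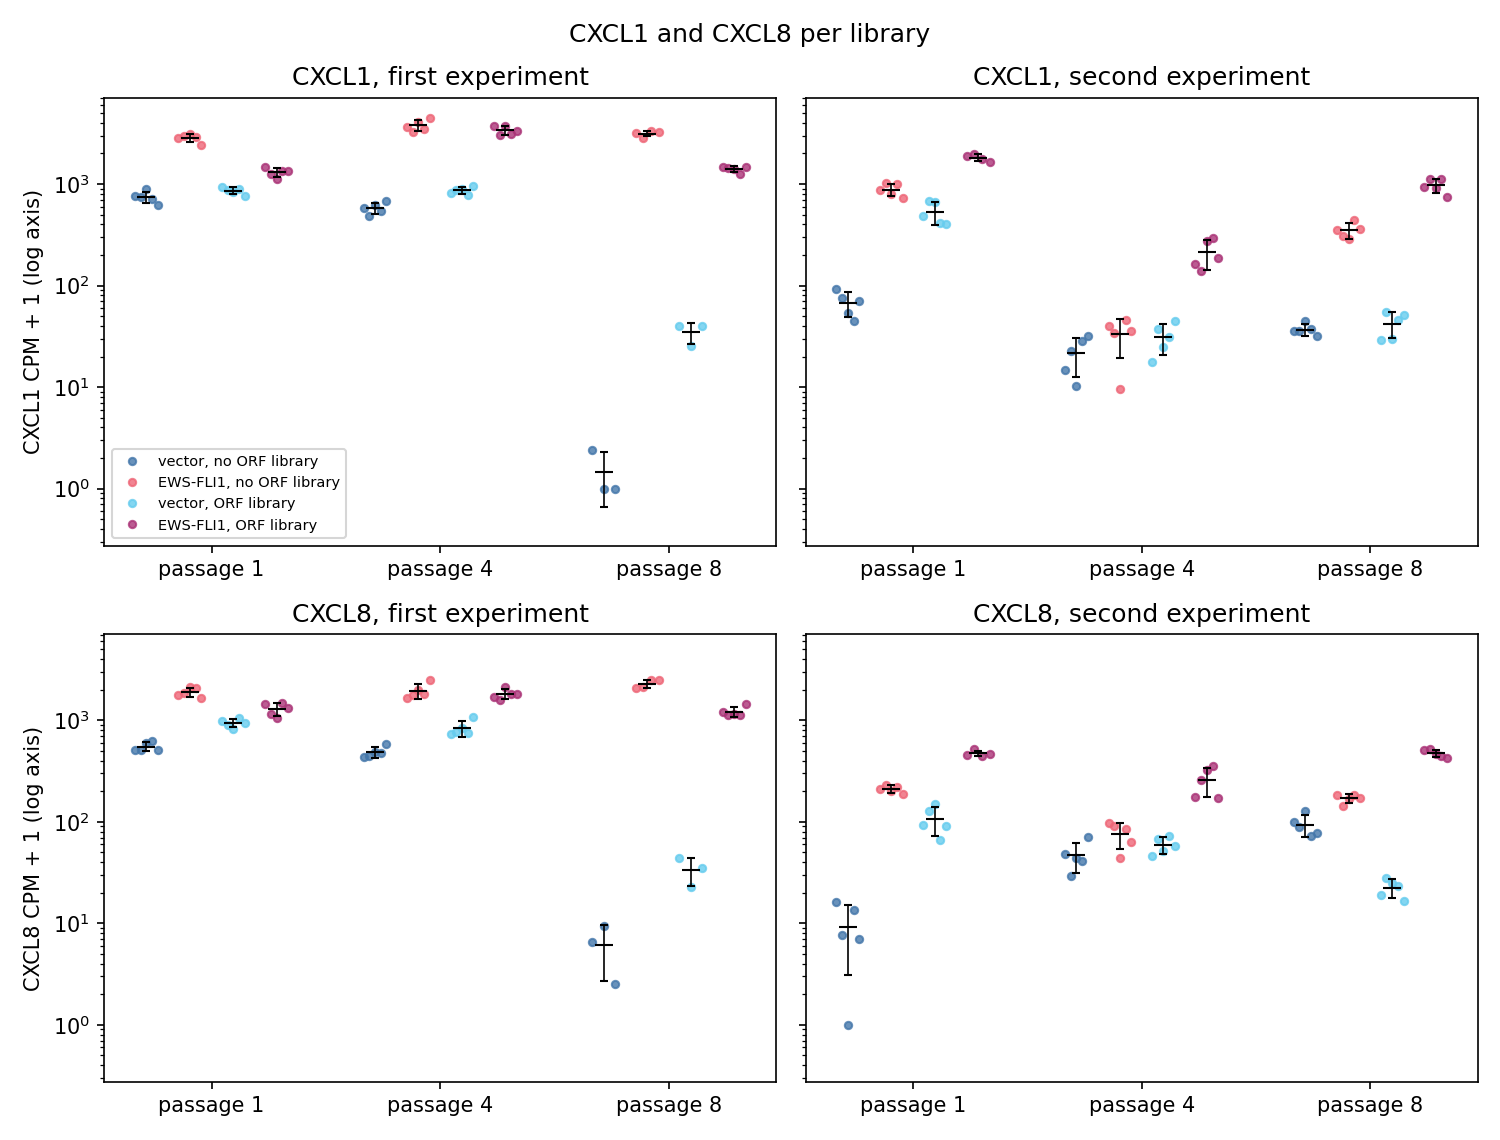
CXCL1 and CXCL8 in each library (points, CPM + 1 on a log axis) by passage and group, with the mean and SD (black bars), for both experiments. At passage 8 with the pool, CXCL8 stood at 1209 ± 134 CPM in EWS-FLI1 cells against 32.8 ± 10.5 in vector cells of the first experiment and at 473 ± 39.7 against 21.4 ± 4.64 in the second.

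The next comparisons ask what the ORF pool changed in cells without the oncogene. At passage 1 (n = 10 and 10) vector cells with the pool had more MTDH (chromosome 8, 97644184 to 97730260), a membrane protein gene often amplified in tumours, than those without it (1.31 ± 0.08). In the first experiment MTDH stood at 3324 ± 127 against 619 ± 43.2 CPM, while in the second its change was 0.19 (adjusted p = 0.505). TSPYL5 (chromosome 8, 97273488 to 97277928), which lies near MTDH, stood at 46.4 ± 16.1 CPM in the first experiment against 3 counts over its 5 libraries without the pool, a ratio of 48.0 (counting interval 16.2 to 235). In the second it rested on 29 counts over 5 libraries against 1 count over 5, a ratio of 28.4 (4.71 to 1159). Whether reads of ORF constructs enter the counts of MTDH and TSPYL5 is not given in the sources used here, so these values cannot be read as levels of the cells' own genes. CXCL8 (1.96 ± 0.13), IL1B (1.85 ± 0.12) and IL6 (1.14 ± 0.12) were higher, OXTR (-1.45 ± 0.11) and ANKRD1 (-1.17 ± 0.09) lower. Actin, SRF and YAP targets had 15 of 18 lower and 0 higher (17 and 0 adjusted over the list alone, adjusted p = 2.85e-33). Matrix genes had 11 of 29 lower and 1 higher (16 and 3 adjusted over the list alone, adjusted p = 4.17e-10) and secreted factors 10 of 21 higher and 4 lower (the same adjusted over the list alone, adjusted p = 2.57e-25). A list of genes of the long arm of chromosome 8 with known roles in cancer, which holds MTDH, RAD21 and MYC, was higher (adjusted p = 0.000664; 0.194 in the second experiment) with 1 of 19 called, MTDH itself (1 adjusted over the list alone). For RAD21 the change was 0.20 ± 0.14, adjusted p = 0.508. All 5 libraries with the pool stood above the 5 without it in the first experiment, and 0 in the second. edgeR called 432 genes (179 higher, 253 lower), 371 and 154 in the single experiments, 48 shared in direction (chance 1.28 and 1.5), and 858, 244 and 252 without replicates a, b and c.

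Vector cells at passage 4 (n = 10 and 10) had 70 genes called between those with and without the pool (44 higher, 26 lower) and 39 without replicate e. The single experiments gave 29 and 170, with 5 shared in direction (chance 0.162 and 0.0507) and 4 called in opposite directions. MTDH rose in both experiments (0.88 ± 0.08), in each library with the pool above every library without it. For RAD21, 2 of 5 libraries with the pool stood above all without it in the first experiment and 1 of 5 in the second, with 0 below. The heparan sulphatase gene SULF1 was higher (0.78 ± 0.13), and ACTA2 (-0.93 ± 0.11), a smooth muscle actin gene, and TXNIP (-0.91 ± 0.16), a regulator of glucose uptake, lower. Of 24 p53 targets 1 was called lower, the cell cycle inhibitor gene CDKN1A (-0.25 ± 0.06, adjusted p = 0.0351), and 0 higher (1 and 0 adjusted over the list alone, adjusted p = 0.000268). The CDKN1A call ended in the first experiment alone (adjusted p = 0.972), without a filter (0.217), with only these libraries (0.123), with libraries thinned to 1000000 counts (0.0506) and without replicates b (0.12), c (0.328), d (0.153) or e (0.162). Secreted factors had 5 higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 2.87e-07). The matrix list (2 higher, 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.00562) was lost with an estimated correlation (adjusted p = 0.213) and without the 6 libraries above 3000000 counts (adjusted p = 0.3).

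At passage 8 (n = 8 and 8) vector cells with the pool held more mRNA of cell division genes than those without it, whose mitosis scores were the lowest of all groups. The score was 3.44 ± 0.15 against 1.41 ± 0.14 in the first experiment (n = 3 each) and 3.80 ± 0.20 against 1.78 ± 0.34 in the second (n = 5 each), with no overlap of libraries. TOP2A (3.14 ± 0.27) and CENPF (2.80 ± 0.18) rose in both experiments, and 17 of 20 mitosis genes were higher and 0 lower (19 and 0 adjusted over the list alone, median 2.86, or 2.29 with bounds; adjusted p = 3.78e-45). Fork protection genes had 6 of 24 higher (8 adjusted over the list alone, adjusted p = 1.02e-05) and replication genes 2 of 25 (5 adjusted over the list alone, adjusted p = 0.000985). Secreted factors had 7 higher and 3 lower (9 and 4 adjusted over the list alone, adjusted p = 1.28e-11; 0.115 in the second experiment, in the other direction). Cholesterol synthesis genes had 1 of 15 lower (6 adjusted over the list alone, adjusted p = 2.83e-05). SERPINB2, a plasminogen activator inhibitor gene (-2.04 ± 0.15), and the desmosome gene DSP (-1.96 ± 0.17) fell. RAD21 did not pass (0.04 ± 0.17, adjusted p = 0.975). The count was 439 (300 higher, 139 lower), 357 and 454 in the single experiments, 77 shared in direction (chance 6.18 and 2.28) and 289 without replicate e.

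The same question was put to EWS-FLI1 cells. At passage 1 (n = 9 and 10) 44 genes passed, 23 higher and 21 lower. MTDH rose to 3324 ± 144 from 616 ± 32 CPM in the first experiment and to 928 ± 115 from 594 ± 13.3 CPM in the second (1.53 ± 0.08). IGF2, a fetal growth factor gene, rose by 2.21 ± 0.19, from 93.1 ± 12.1 to 199 ± 36.1 CPM and from 3.52 ± 1.83 to 41.9 ± 9.27 CPM. The overlapping INS-IGF2 carries the same values, so these reads are not assigned to one gene. POSTN fell (-0.56 ± 0.07). The mitosis list was lower (median -0.29, adjusted p = 3.6e-09) with 0 of 20 genes called by edgeR over all genes, 4 adjusted over the list alone, 9 at an unadjusted p under 0.05 and 0 called by DESeq2. The secreted factors, 1 called higher (2 without the 6 libraries above 3000000 counts) and 0 lower (4 and 1 adjusted over the list alone) and up in the average (adjusted p = 0.00018), went down in the first experiment (adjusted p = 1.3e-08), and the matrix list (0 higher, 4 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.0283) was lost with an estimated correlation (adjusted p = 0.321) and without those 6 libraries (adjusted p = 0.0889). The chromosome 8 list was higher (adjusted p = 0.000893) with MTDH as its single called member (1 adjusted over the list alone), while its median was -0.0091. The value of RAD21 was -0.02 ± 0.14, adjusted p = 1. The experiments gave 70 and 40 genes, with 7 shared in direction (chance 0.0787 and 0.0588) and 8 called in opposite directions. The count was 27, 22 and 26 without replicates a, c and d and 108 when these libraries alone were fitted.

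Counts for EWS-FLI1 cells at passage 4 (n = 10 and 10) rested on a few libraries: 722 genes (387 higher, 335 lower) became 135 without the 6 libraries above 3000000 counts, 131 without replicate c and 124 without replicate d. The first experiment alone gave 7 genes and the second 1541, and 3 were shared in direction (chance 0.337 and 0.207). MTDH rose (0.42 ± 0.08), though not past the threshold in the second experiment alone (adjusted p = 0.336). There 3 of 5 libraries with the pool stood above all without it in MTDH. The other 2, replicates c and d with 498 and 503 CPM, stood below all, and both are above 3000000 counts. ACTG2 (-0.62 ± 0.06) and MMP1 (-0.36 ± 0.05) fell in both experiments. The insulin-like growth factor binding protein gene IGFBP5 was -0.15 in the first experiment and 2.06 in the second. Actin, SRF and YAP targets had 9 of 18 lower and 0 higher (14 and 1 adjusted over the list alone, adjusted p = 4.58e-14; 0.752 in the first experiment). The mitosis list was higher (adjusted p = 0.00301), with 3 of 20 called and 0 lower (the same adjusted over the list alone), as was the chromosome 8 list (adjusted p = 0.0106), with 3 of 19 called (4 adjusted over the list alone). Without the 6 libraries above 3000000 counts edgeR called 5 actin, SRF and YAP targets lower, 1 gene of the chromosome 8 list higher (adjusted p = 0.000213) and 0 of 20 mitosis genes, 4 of them at an unadjusted p under 0.05. The mitosis list then had adjusted p = 0.0153, and 0.0661 with an estimated correlation, and DESeq2 was not run there. Secreted factors had 9 higher and 4 lower (9 and 5 adjusted over the list alone). Their test was up (adjusted p = 0.00255) with a mean of 0.21 and a median of -0.05, and down in the first experiment (adjusted p = 1.99e-05). RAD21 did not pass (-0.27 ± 0.14, adjusted p = 0.217).

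At passage 8, EWS-FLI1 cells with the pool (n = 10) held far more mRNA of cell division genes than those without it (n = 9). MKI67 rose by 2.65 ± 0.19, from 27.4 ± 11.4 to 244 ± 34.4 CPM in the first experiment and from 29.3 ± 37.0 to 67.5 ± 11.4 CPM in the second. Without replicate b of the cells without the pool in the second experiment, the library of 31525 counts, the lower level was 12.8 ± 4.08 CPM and the log2 change over both experiments 2.72. All 20 mitosis genes were higher (20 adjusted over the list alone, median 2.26, adjusted p = 1.91e-78; 2.46e-32 in the second experiment), with CENPF at 2.38 ± 0.11 and the mitotic kinase gene AURKB at 3.13 ± 0.39. Of 25 replication genes, 22 rose (22 adjusted over the list alone, median 1.46, adjusted p = 7.02e-20), and of 24 fork protection genes, 13 (18 adjusted over the list alone, adjusted p = 7.23e-14), with none lower in either, and the helicase subunit MCM5 (2.12 ± 0.26) and RRM2 (2.04 ± 0.19), which supplies deoxynucleotides, are examples. Cohesin genes had 7 of 14 higher and 0 lower (8 adjusted over the list alone, adjusted p = 3.02e-06), with SMC3 at 1.07 ± 0.12 and ESCO2 at 2.91 ± 0.44.

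RAD21 was itself higher with the pool at passage 8 (0.82 ± 0.16, adjusted p = 2.12e-05), though whether reads of a construct enter its counts is not given. In the first experiment it stood at 92.5 ± 10.8 CPM with the pool, all 5 libraries above the 4 without it at 38.4 ± 14 CPM. In the second it stood at 58.2 ± 14.1 against 49.6 ± 15.1 CPM and was not called (0.32, adjusted p = 0.562), and the effects differed (adjusted p = 0.0326). Without replicate b of the cells without the pool there, a library of 31525 counts with 71.4 CPM of RAD21, the lower level was 44.2 ± 10.3 CPM (n = 4). The p53 targets had 6 of 24 lower, CDKN1A at -0.44 ± 0.07 among them (-0.04 and not called in the second experiment), and 0 higher (10 lower adjusted over the list alone, adjusted p = 0.0012; 0.23 in the second experiment). Cholesterol synthesis genes had 8 of 15 lower (10 adjusted over the list alone, adjusted p = 0.000108), 4 with DESeq2 size factors. Actin, SRF and YAP targets had 8 of 18 lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 1.65e-11). The amino acid and unfolded protein response list had 3 of 14 higher and 0 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0158; 0.575 in the first experiment, in the other direction). PHGDH (1.33 ± 0.18) and PSAT1 (1.36 ± 0.24), enzymes of serine synthesis, were among its higher members, although PSAT1 did not pass in the first experiment alone (adjusted p = 0.157). Secreted factors had 2 higher and 10 lower (5 and 10 adjusted over the list alone). Their test was down (adjusted p = 0.00805) with a mean of -0.15 and a median of 0.06, and up in the second experiment (adjusted p = 1.63e-09). Matrix genes, 7 higher and 9 lower (8 and 10 adjusted over the list alone, adjusted p = 0.0286), lost their call with an estimated correlation (adjusted p = 0.288) and went up in the second experiment (adjusted p = 0.000854). CCND2, a cyclin gene (-1.85 ± 0.15), and the secretogranin gene SCG2 (-1.58 ± 0.19) were lower. In total 1479 genes passed, 749 higher and 730 lower (903 and 555 with DESeq2 size factors), 1850 in the first experiment and 472 in the second, 190 shared in direction (chance 25.7 and 17.4).

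**Figure D4:**
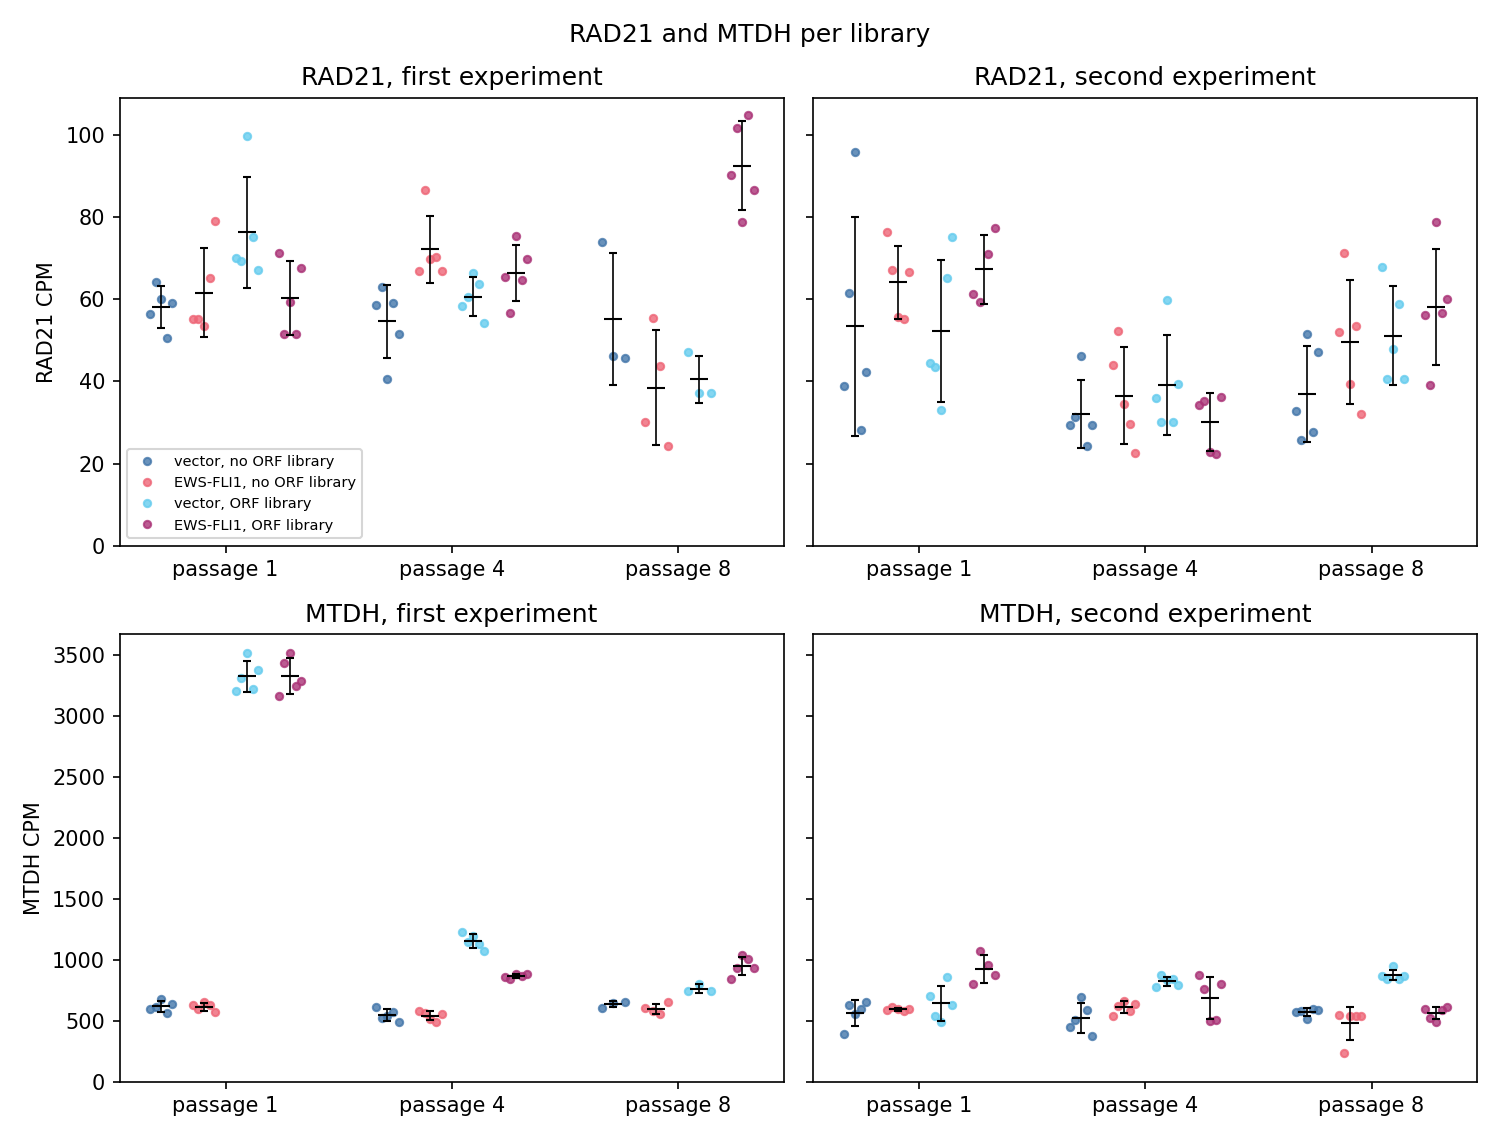
RAD21 and MTDH in each library (points, CPM) by passage and group, with the mean and SD (black bars), for both experiments. RAD21 stood at 92.5 ± 10.8 CPM in EWS-FLI1 cells with the pool at passage 8 of the first experiment against 38.4 ± 14 without it, and MTDH at 3324 ± 144 against 616 ± 32 CPM at passage 1.

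How the cultures changed with time was read from passage 8 against passage 1 in each kind of cell. In the first experiment the mean mitosis scores of the groups were 5.53 to 5.79 at passage 1 and 5.49 to 5.96 at passage 4. In the second they were 5.85 to 6.27 at passage 1 and already 3.39 to 4.00 at passage 4, lower in every kind of cell. Values at passage 4 over both experiments thus average cultures with unlike scores. Vector cells without the pool (n = 8 and 10) lost mRNA of all 20 mitosis genes (20 adjusted over the list alone, median -5.29, or -4.69 with bounds; adjusted p = 1.4e-79), of 23 of 25 replication genes (23 adjusted over the list alone, adjusted p = 1.02e-16) and of 16 of 24 fork protection genes (16 adjusted over the list alone, adjusted p = 3.74e-12). CENPF fell by 4.83 ± 0.15 and TOP2A fell by 5.53 ± 0.21. CDK1, the mitotic kinase gene, had no count at passage 8 and was at least 24.7-fold lower in the first experiment and at least 34.3-fold in the second. The p53 targets had 13 of 24 higher, with CDKN1A at 0.66 ± 0.07, and 1 lower (the same adjusted over the list alone, adjusted p = 0.00113; 0.35 in the second experiment). Hypoxia and glycolysis genes had 10 of 13 and 1 (the same adjusted over the list alone, adjusted p = 2.8e-05). CCND2 (3.60 ± 0.16), the vasoconstrictor gene EDN1 (3.41 ± 0.17) and ANKRD1 (2.85 ± 0.10) rose. Secreted factors (7 higher, 8 lower, 7 and 9 adjusted over the list alone, median 0.08, mean -0.62) tested down (adjusted p = 0.0243), which was lost with an estimated correlation (adjusted p = 0.0627) and without the 6 libraries above 3000000 counts (adjusted p = 0.0714) and turned up in the second experiment (adjusted p = 6.5e-08). Matrix genes (15 higher, 7 lower, 15 and 8 adjusted over the list alone, median 0.27, mean -0.07) tested up (adjusted p = 0.00604), were lost with an estimated correlation (adjusted p = 0.206) and went down in the second experiment (adjusted p = 0.0108). RAD21 was not called (-0.22 ± 0.16, adjusted p = 0.317). The count was 3264 genes (1663 higher, 1601 lower), 2862 and 2475 in the single experiments, 925 shared in direction (chance 171 and 180).

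EWS-FLI1 cells without the pool (n = 9 and 10) lost the same 20 mitosis genes with a smaller median of -2.50 (20 adjusted over the list alone, adjusted p = 8.96e-68) and 23 of 25 replication genes (24 adjusted over the list alone, adjusted p = 3.17e-16). RAD21 fell by 0.66 ± 0.15 (adjusted p = 0.000257; 0.0895 without replicate e), with -0.77 and -0.54 in the single experiments. The cohesin list, 5 of 14 lower (5 adjusted over the list alone, adjusted p = 0.00351), was lost with an estimated correlation (adjusted p = 0.0566). The acute phase gene SAA1 rose by 5.16 ± 0.36 and the complement gene C3 by 4.01 ± 0.22, and 11 of 21 secreted factors were higher and 5 lower (the same adjusted over the list alone, adjusted p = 3.25e-06). Genes called were 2681 (1341 higher, 1340 lower), 1193 and 2449 in the single experiments, 634 shared in direction (chance 70.5 and 74.4).

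Vector cells with the pool (n = 8 and 10) also lost all 20 mitosis genes (20 adjusted over the list alone, median -2.37, adjusted p = 6.35e-43) and 22 of 25 replication genes (23 adjusted over the list alone, adjusted p = 1.53e-13). Actin, SRF and YAP targets had 17 of 18 higher and 1 lower (the same adjusted over the list alone, adjusted p = 1.38e-25), with ANKRD1 at 3.43 ± 0.10. Hypoxia and glycolysis genes had 10 of 13 higher, with the glucose transporter gene SLC2A1 at 1.53 ± 0.10 (10 adjusted over the list alone, adjusted p = 2.86e-11). CXCL1 (-4.24 ± 0.14) and CXCL8 (-3.70 ± 0.16) fell. RAD21 fell in the average (-0.38 ± 0.15, adjusted p = 0.0352), with -0.94 in the first experiment and 0.17 in the second. The call ended with DESeq2 (adjusted p = 0.0502) and without replicates b (0.0613), c (0.0891), d (0.0664) or e (0.229). The cohesin list, 6 of 14 lower (6 adjusted over the list alone, adjusted p = 0.0133), was lost with an estimated correlation (adjusted p = 0.0936). The count was 3692 genes (1939 higher, 1753 lower), 2627 and 3385 in the single experiments, 1001 shared in direction (chance 235 and 206). Without the 6 libraries above 3000000 counts, 2 of which are vector libraries with the pool at passage 1, the second experiment gave 1804.

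EWS-FLI1 cells with the pool (n = 10 and 9) were the one kind of cell in which edgeR called 0 of 20 mitosis genes between passages 1 and 8, with 5 at an unadjusted p under 0.05 and 0 by DESeq2. The experiments went opposite ways. The mitosis score rose from 5.53 ± 0.14 to 6.58 ± 0.09 in the first and fell from 5.85 ± 0.09 to 4.79 ± 0.24 in the second. RAD21 was 0.61 in the first (adjusted p = 0.00905) and -0.24 in the second (adjusted p = 0.62), and 0.19 ± 0.15 over both (adjusted p = 0.522). Cholesterol synthesis genes had 8 of 15 lower (12 adjusted over the list alone, adjusted p = 8.31e-10), such as FDFT1 (-0.74 ± 0.11), which did not pass in the second experiment alone (adjusted p = 0.12). Hypoxia and glycolysis genes had 5 of 13 higher (5 adjusted over the list alone, adjusted p = 0.000121). CDCP1, a surface protein gene, rose in both experiments (2.83 ± 0.18), and THY1 (-2.16 ± 0.16) and JAG1, a Notch ligand gene (-1.90 ± 0.23), fell. FLI1 fell (-1.16 ± 0.29, adjusted p = 0.00273), which was not called in the second experiment or without replicate a (adjusted p = 0.409). The count was 960 genes (446 higher, 514 lower), 1290 and 1174 in the single experiments. In both, 128 moved the same way (chance 37.9 and 37.3) and 234 opposite ways.

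Whether the pool acted differently in EWS-FLI1 and vector cells at passage 8 was tested as an interaction, positive where the effect of the pool was higher in EWS-FLI1 cells. RAD21 had 0.78 ± 0.24, adjusted p = 0.0396, with 1.78 in the first experiment and -0.22 in the second, a difference itself called (adjusted p = 0.00247). The cohesin list was positive (adjusted p = 8.26e-05; 0.701 in the second experiment) with 4 of 14 called (6 adjusted over the list alone), SMC3 (0.67 ± 0.17) and SMC1A (0.82 ± 0.22) among them. So was the replication list (adjusted p = 1.16e-05; 0.701 in the second experiment) with 4 of 25 (5 adjusted over the list alone), such as MCM5 (1.98 ± 0.44). The mitosis list was not called (median -0.50, adjusted p = 0.48), with 1 of 20 positive and 0 negative (2 and 2 adjusted over the list alone). In the vector comparison 4 of its genes had a group without counts. With these at their bound its median rise with the pool was 2.29 in vector and 2.26 in EWS-FLI1 cells. None of SMC3 (-0.13), SMC1A and MCM5 passed in the second experiment alone. SMC3 ended without replicates b (adjusted p = 0.0701), c (0.139) or e (0.0858), and SMC1A without c (0.113) or e (0.349). Secreted factors were negative with 11 of 21 called (11 and 1 positive adjusted over the list alone, adjusted p = 7.11e-21), but positive in the second experiment (adjusted p = 1.53e-05). Genes known as induced by EWS-FLI1 had 2 of 14 negative (2 adjusted over the list alone, adjusted p = 0.00703), and neural genes 3 of 8 (4 adjusted over the list alone, adjusted p = 6.35e-11), with STMN2 at -3.71 ± 0.27. The RAD21 call ended without a filter (adjusted p = 0.0847), with the stricter filter (0.0555), with libraries thinned to 1000000 counts (0.0821) and without replicates b (0.0713), c (0.141), d (0.0518) or e (0.464). Of 323 genes called, 94 were positive and 229 negative (123 and 180 with DESeq2 size factors). The single experiments gave 689 and 170, with 25 shared in direction and 40 called in opposite directions. The count was 176 and 158 without replicates c and e.

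Whether the EWS-FLI1 effect without the pool changed from passage 1 to 8 was tested in the same way. DIO2, lower with EWS-FLI1 at passage 1, had a change of 5.69 ± 0.20, TOP2A of 3.23 ± 0.29, CENPF of 2.50 ± 0.21 and IGFBP5 of 2.73 ± 0.08, while POSTN (-1.71 ± 0.10), FST (-1.83 ± 0.17) and DSP (-2.77 ± 0.26) were negative. Mitosis genes had 14 of 20 positive and 0 negative (18 and 0 adjusted over the list alone, adjusted p = 7.61e-27). Secreted factors had 12 of 21 and 3 (13 and 4 adjusted over the list alone, adjusted p = 7.69e-21; 0.0825 in the second experiment, in the other direction). Matrix genes had 4 of 29 and 10 (5 and 10 adjusted over the list alone, adjusted p = 2.1e-06). RAD21 had -0.43 ± 0.22, adjusted p = 0.314. Of 608 genes called, 340 were positive and 268 negative. The single experiments gave 809 and 296, with 53 shared in direction and 53 called in opposite directions. The count was 404 without replicate c and 370 without replicate e.

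Of 360 tests of lists over all comparisons 145 were called, and 134 of these held with an estimated correlation. Of the 145, 70 were not called in the second experiment alone and 20 in the first. As lists, chondrogenic, interferon and immediate early genes were called in no comparison, although single members of each passed in some (smallest adjusted p = 0.319, 0.19 and 0.303). Adipogenic genes (2 tested) and blood cell markers (1 tested) were too few for a test, and no epithelial, endothelial or skeletal muscle marker and no mitochondrially encoded gene was among the tested genes. By chromosome, camera called 0 of 414 tests (12 had an unadjusted p under 0.05), with 0 called in the first experiment alone and 1 in the second, chromosome 19 in the passage 1 comparison of EWS-FLI1 and vector cells with the pool (adjusted p = 0.0082). No median of a chromosome stood more than 0.167 from that of all genes. Chromosome 8, with 346 tested genes, had a median of -0.0073 between EWS-FLI1 cells with and without the pool at passage 8 (adjusted p = 0.936), and of -0.07 and 0.07 in the single experiments. With counts summed per group, which leaves each experiment as 1 replicate, edgeR called 715 genes for vector cells without the pool and 188 for those with it between passages, and 0 to 2 genes in the other comparisons, where 70 to 1387 had an unadjusted p under 0.05 and DESeq2 on the libraries called 48 to 2433.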

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

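The tests of other chromosome 8 genes and of a slower loss of cycling cells, and the fits without the 6 libraries above 3000000 counts and with libraries thinned to 1000000, were chosen only after the results had been seen, and that of GC content after these 6 libraries had been seen to stand apart.

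Of 154 sets of values per group that were tested for a library far from the others, 11 held one, where chance gives about 1 in 20. In EWS-FLI1 cells without the pool, replicate e of the first experiment at passage 4 had 2042091 counts (others 1048198 to 1321754) and replicate a of the second at passage 1 had 1555956 (495168 to 718297). In vector cells without the pool of the second experiment, replicate a at passage 1 had 8336398 counts (216911 to 616980) and replicate e at passage 4 had 6329571 (327601 to 994908). FLI1 stood at 15.5 CPM in replicate c of EWS-FLI1 cells with the pool at passage 8 of the first experiment (6.65 to 7.95). EWSR1 stood at 52.3 CPM in replicate d of vector cells with the pool at passage 4 of the first experiment (70.6 to 73) and at 112 CPM in replicate b of EWS-FLI1 cells without it at passage 1 of the second (78.3 to 87.0). RAD21 stood at 99.8 CPM in replicate c of vector cells with the pool at passage 1 (67.2 to 75.2) and at 86.7 CPM in replicate b of EWS-FLI1 cells without it at passage 4 (66.9 to 70.4), both in the first experiment. Replicate b of EWS-FLI1 cells without the pool at passage 8 of the second experiment, the library of 31525 counts, had 95.2 CPM of MKI67 (7.42 to 17.3) and a mitosis score of 1.89 (3.16 to 3.33).

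The effect of a comparison differed between the experiments for some genes in each of the 18 (edgeR, adjusted over all genes). For EWS-FLI1 against vector these were 79, 240 and 883 genes without the pool and 504, 240 and 841 with it, at passages 1, 4 and 8. For the pool against none they were 151, 62 and 318 in vector cells and 69, 290 and 651 in EWS-FLI1 cells. For passage 8 against 1 they were 1607 and 698 without the pool and 1893 and 1393 with it, in vector and EWS-FLI1 cells. The interaction at passage 8 gave 398, and the change of the EWS-FLI1 effect with passage 514. Genes called in both experiments but in opposite directions numbered, in the same order, 6, 14 and 59, and 19, 9 and 35 for EWS-FLI1. For the pool they were 3, 4 and 41, and 8, 1 and 70. Between passages they were 324 and 97, and 280 and 234, with 40 for the interaction and 53 for the change with passage.

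Between EWS-FLI1 cells with and without the pool at passage 4, the second experiment called 1541 genes and the first 7. Sequencing depth alone is argued against, since 948 genes were called in the second experiment with libraries thinned to 1000000 counts. Without the 6 libraries above 3000000 counts that number was 250, which is consistent with a difference between library batches. Within each of the 4 groups that hold them, these libraries differed from the rest by a like profile (r = 0.853 to 0.917 across 3466 genes), which followed the GC content of the last 500 bases of the transcript (r = -0.41 over 3431 genes, which are not independent replicates). A biological difference between the experiments stays open and was not tested.

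MTDH and TSPYL5, near each other on chromosome 8, were higher with the pool, and whether their reads come from ORF constructs is open, since the labels do not name the pool's members. A copy gain of the segment is argued against in EWS-FLI1 cells at passage 8, where the 31 other genes within 5000000 bases had a median log2 change of 0.0095 (95% bootstrap interval -0.0982 to 0.114) and MTDH one of 0.39. In these EWS-FLI1 cells MTDH stood above all libraries without the pool in 5 of 5 libraries of the first experiment and 3 of 5 of the second. At passage 4 in these cells the median was 0.16 (0.0671 to 0.28) with 2 of the 31 called higher, beside 0.42 for MTDH, so a gain that accounts for part of that change is not excluded there. Of the 24 other genes higher with the pool in at least 4 of 6 comparisons, 1 lay on chromosome 8 (odds ratio 1.22, 95% interval 0.0295 to 7.56, Fisher exact two-sided p = 0.569), which leaves open whether reads of constructs raise further genes of that chromosome. The test was first run with MTDH and TSPYL5 included (Fisher exact p = 0.0594), and they were taken out after that value had been seen.

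In EWS-FLI1 cells at passage 8 the mitosis genes were higher with the pool by a median of 2.26. Library size is argued against, with a median of 2.19 after 113 libraries were thinned to 100000 counts, and so is a single library, with medians of 2.25 to 2.29 when each letter was left out. A slower loss of cycling cells in culture is argued against in the first experiment, where the list rose with the pool from passage 1 to 8 by a median of 0.990 (adjusted p = 3.85e-26), every library of passage 8 above all of passage 1. In the second it stays open as a biological explanation, as the list changed by -1.06 with the pool and -3.19 without it. Neither outcome set for its test was met there, since the list was lower with the pool at passage 1 (camera adjusted p = 6.87e-08, and 3.6e-09 over both experiments), and its score rose with the pool from 4.00 ± 0.17 at passage 4 to 4.79 ± 0.24 at passage 8.

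Other splits of the same libraries, 100 per comparison within experiments with the real one included, were tested with limma-voom. They exchange single libraries, so chance is judged among these libraries only, as the labels do not say whether the letters are independent. For EWS-FLI1 against vector, chance was excluded in all 6 comparisons, as 1 of 100 splits, the real one, was as large. The real split called 535, 413 and 1412 genes without the pool (highest other 58, 101 and 750) and 1208, 1429 and 2035 with it (907, 839 and 861), at passages 1, 4 and 8. For the pool in vector cells at passage 1 chance was not excluded, as 6 of 100 splits called as many as the real 240 (highest other 699), though without the 6 libraries above 3000000 counts the real split called 396 and the highest other 18. It was excluded at passages 4 and 8, with 72 against 68 and 484 against 186. In EWS-FLI1 cells it was excluded with 69 against 59 at passage 1 and 1691 against 82 at passage 8. At passage 4 in EWS-FLI1 cells the real split called 1259 and the highest other 1745, with 4 of 100 splits as large. That met the limit set beforehand, but without adjustment over the 18 comparisons, so chance is not held as excluded there. For passage 8 against 1 it was excluded with 3277 against 1681 and 2989 against 1709 without the pool and 3861 against 1872 and 1181 against 147 with it. For the interaction the real split called 437 genes and the highest other 429, and for the change with passage 642 and 752 (2 of 100 splits as large). These splits exchanged pool labels within each oncogene, or oncogene labels within each passage, so they assume no effect at all. They cannot exclude chance for a difference between 2 effects. The median of the other splits was 0 genes in every comparison. Splits that call many genes can lie close to the real one and share its signal, so they need not show another structure of the libraries. At passage 4 in EWS-FLI1 cells the highest other split was 65, and the real one 83, without the 6 libraries above 3000000 counts.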

How the results depend on the processing

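The fits without the 6 libraries above 3000000 counts, without the library with the lowest total and with libraries thinned to 1000000 counts were chosen only after the data had been seen.

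With totals from 31525 to 8557124, depth limits weakly expressed genes, and 10062 of 22794 genes were tested. The replicate letters were not taken as pairs, since deviations from the group means correlated above 0.1 in 59 of 144 pairs of libraries with one letter, and in every pair in 2 of 32 sets, both in the first experiment (EWS-FLI1 against vector without the pool at passage 4 and with it at passage 8). Best with their own letter correlated 69 of 144, where chance gives 30.3, a hint from the data of something shared within letters. A replicate block moved no count of genes by more than 1.5 times and ended 2 list calls, replication at passage 8 without the pool (adjusted p = 0.0521) and between EWS-FLI1 cells with the pool and without at passage 4 (0.0557). The block gives each letter the same shift in both experiments and at all passages. It therefore cannot take up what libraries of one letter share within an experiment and passage, and pairing of that kind was not modelled. Most of the genes named were chosen for passing in each experiment or for the smallest adjusted p, so that they last under a setting, above all in a single experiment, is largely set by that choice. Of 376 gene results called, scaling with DESeq2 size factors, a replicate block and leaving out the library with the lowest total lost 0. Other losses were 2 without a filter and 1 of 374 with the stricter filter, 2 of 368 with DESeq2, 1 of 345 with only the libraries compared, 3 to 9 when a replicate letter was left out, and 2 each of 375 without the 6 libraries and of 376 with thinned libraries. The first experiment alone lost 5 and reversed 2, and the second lost 20 and reversed 4. Counts summed per group, where each experiment is 1 replicate, lost 350. In the simulation, which held no difference between the experiments, such sums found 79.4% of 2-fold and 98.5% of 4-fold changes. That argues against fewer replicates as the only cause. In the fit of sums the spread left over is the disagreement of the conditions between the experiments, so it enters the p-values. The effect differed between the experiments for 62 to 1893 genes in each comparison. How many of the lost results this accounts for was not tested. Of 145 list calls, an estimated correlation lost 11. The first experiment alone lost 20 and reversed 2, and the second lost 70 and reversed 6.

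In what follows counts are given for the comparisons in the order of the text, as EWS-FLI1 against vector without the pool at passages 1, 4 and 8, with the pool at passages 1, 4 and 8, the pool against none in vector cells and in EWS-FLI1 cells at the same passages, passage 8 against 1 in vector and EWS-FLI1 cells without and with the pool, the interaction and the change with passage. Counts by sums per group were 0, 0, 1, 1, 0, 2, 0, 0, 0, 0, 0, 0, 715, 0, 188, 0, 0 and 0 genes by edgeR, where an unadjusted p under 0.05 gave 273, 198, 779, 427, 561, 1081, 83, 77, 310, 70, 414, 849, 2489, 1387, 2379, 486, 279 and 342, and DESeq2 on libraries called 426, 322, 1134, 676, 709, 1640, 395, 76, 384, 48, 456, 1240, 3035, 2433, 3309, 792, 259 and 532. Leaving out each letter gave ranges of 350 to 430, 224 to 306, 849 to 1123, 340 to 736, 312 to 1203, 1368 to 1618, 244 to 858, 39 to 61, 289 to 389, 22 to 33, 124 to 1041, 1017 to 1295, 2701 to 3004, 2086 to 2366, 2646 to 3515, 647 to 889, 158 to 248 and 370 to 497.

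Other counts that moved by more than 1.5 times were as follows, and the cause was not tested. For EWS-FLI1 against vector without the pool, the first experiment alone gave 274 genes at passage 1 and the second 321 at passage 1 and 541 at passage 8. With the pool, the first gave 230 and 254 at passages 1 and 4, and the second 1410 at passage 1 and 488 at passage 8, while without the 6 libraries there were 377 and 335 at passages 1 and 4. For the pool in vector cells, the first gave 29 at passage 4, the second 154 and 170 at passages 1 and 4, and a fit of only the libraries compared 264 at passage 1. In EWS-FLI1 cells, the first gave 70 and 7 at passages 1 and 4, the second 1541 and 472 at passages 4 and 8, and only the libraries compared 108 and 301 at passages 1 and 4. At passage 4 there, DESeq2 gave 456, thinned libraries 380, and the fit without the 6 libraries 135. For passage 8 against 1 in EWS-FLI1 cells without the pool the first gave 1193. For the interaction the first gave 689 and the second 170, and for the change with passage the second gave 296. With the 6 libraries left out as well, the single experiments moved by more than 1.5 times from their own counts in 7 comparisons. For EWS-FLI1 against vector at passage 4 without the pool the second gave 235, and with the pool it gave 320 and 255 at passages 1 and 4, where the first gave 406 at passage 4. For the pool against none the second gave 111 in vector cells at passage 4 and 68 and 250 in EWS-FLI1 cells at passages 1 and 4. For passage 8 against 1 in vector cells with the pool it gave 1804.

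Results that reversed in a single experiment, where the cause was not tested, were these. In the second experiment RAD21 had 0.17 between passages in vector cells with the pool and -0.22 in the interaction, SMC3 had -0.13 in the interaction, and SPARC 0.0076 at passage 8 without the pool. In the first, IL1B had -0.048 at passage 1 with the pool, and IGFBP5 -0.15 at passage 4 between EWS-FLI1 cells with the pool and without. By camera, matrix genes reversed in the second experiment at passage 8 with the pool (adjusted p = 0.0174), between EWS-FLI1 cells with the pool and without (0.000854) and between passages in vector cells without the pool (0.0108). Secreted factors reversed between EWS-FLI1 cells with the pool and without in the first experiment at passages 1 (1.3e-08) and 4 (1.99e-05) and in the second at passage 8 (1.63e-09), and in the second between passages in vector cells without the pool (6.5e-08) and in the interaction (1.53e-05).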

Other observations

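The genes that recur were chosen only after their values had been seen, as those called in at least 4 of the 6 comparisons of cells with and without the pool.

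Some genes recurred between the comparisons of cells with and without the pool. MTDH was higher with the pool in all 6 comparisons, with log2 changes of 1.31, 0.88 and 0.44 in vector cells and 1.53, 0.42 and 0.39 in EWS-FLI1 cells at passages 1, 4 and 8. In the second experiment not all libraries with the pool stood above those without it in 3 of these. They were 2 of 5 in vector cells at passage 1 and 3 of 5 in EWS-FLI1 cells at passages 4 and 8. At passage 8 there, MTDH ran from 494 to 616 CPM with the pool, against 542 ± 4.31 without it when replicate b was left out (n = 4). Higher in 5 were the bradykinin receptor gene BDKRB1, CDCP1, the growth factor gene MDK, the protease inhibitor gene TFPI2 and TSPYL5. In at least 4 of the 6, 26 genes were higher and 19 lower, where lists drawn independently would give 0.0288 and 0.0148. The comparisons use different libraries, but of successive passages in the same 2 experiments, so a difference present at passage 1 can recur. Their lists are thus not independent, and the excess over independent lists is no support by itself. Other genes higher in 4 included the cytokine genes IL1B, IL6 and CXCL6, the growth factor genes FGF2 and IGF2, the adhesion gene ICAM1, SOD2, IGFBP5 and SULF1. Lower in 5 were the smooth muscle actin gene ACTA2, CCDC80, FHL1 and PRSS23, and lower in 4 were FN1, the fibronectin gene, the caldesmon gene CALD1, COL8A1, IGFBP4 and ITGA3, among others.

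TSPYL5 had no count in any library without the pool at passages 4 and 8 in EWS-FLI1 or vector cells. In EWS-FLI1 cells it was at least 23.5-fold higher with the pool in the first experiment and at least 6.07-fold in the second at passage 4, and at least 10.5-fold and 17.7-fold at passage 8, each against 3 counts over the group.

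The first 4 principal components of the libraries held 24.7, 16.9, 9.61 and 6.39% of the variance.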
